A study of Homo sapiens with 6 samples.

How the data were processed

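The samples were 1 p63 chromatin immunoprecipitation and 1 input library from ME-180 cells, and 4 RNA libraries: ME-180 control, ME-180 labelled knockdown, SiHa vector and SiHa p63 overexpression. Groups were taken from the titles and characteristics in the labels, with 1 library per group. Per the labels' protocols, total RNA was extracted with TRIzol, and DNA for immunoprecipitation was isolated with an antibody. The submitters' processing notes name TopHat, Cufflinks and DESeq2 and the genome build hg19, without roles or versions. The counting method, strand setting and peak caller are not given in the sources used here.

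The authors deposited 1 table per RNA experiment with whole-number counts per RefSeq transcript, 15189 transcripts for ME-180 and 16600 for SiHa. Transcripts of 1 gene had overlapping counts, as for TP63, so a read can enter several rows, and transcripts with 0 counts in both libraries were absent. The ratio of adjusted to raw p at the smallest p in the SiHa table was 29802, above its 16600 rows, so that table holds part of a larger one. In ME-180 the ratio was 14950.5 against 15189 rows, which does not show this. That table still lacks common genes, among them RPS2, which had 188540 counts in the SiHa vector library. It has rows for 13 of 25 housekeeping and 15 of 36 cell cycle genes of the lists below. A gene without a row cannot be read as not expressed, and neither table's totals were taken as library depths. The deposited log fold change is on the log2 scale: with a scaling taken from the same column, it matched the log2 ratio of edgeR's exact test within 5.84e-06 in ME-180 and 1.76e-06 in SiHa. That ratio includes a small prior count, so it departs from the plain ratio of the counts where these are low and is finite at 0. The authors' deposited p-values were recomputed with the exact test of edgeR 4.0.16 at several preset biological coefficients of variation. At 0.2, 99.987% of p-values in ME-180 and 100% in SiHa lay within 0.01 log10 units, and at 0.1, 0.3 and 0.4 between 8.80% and 24.0% did. The peak table gave chromosome, start and end as deposited, with no score, and 1 stray header line inside it was skipped. All 6466 peaks start on a multiple of 50 bp and end 1 below one, and coordinates are printed as the file gives them.

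Gene names came from the tables. For 32 rows in ME-180 and 31 in SiHa a spreadsheet date stood in place of the name, and the RefSeq transcript identifier gave the name through a reference table of another build, from which no coordinates were used. Counts were divided by the total of the table's rows and scaled to 1000000 (CPM). Each gene was represented by its transcript with the highest summed CPM over the 2 libraries (8798 genes in ME-180, 9490 in SiHa). Log2 ratios were taken of CPM plus a pseudocount of 1, which shrinks the ratios of low genes. A gene was called higher or lower at a ratio of at least 2-fold with at least 1 CPM in at least 1 of the 2 libraries. No p-value was computed, since 1 library per group allows no test of the conditions. Exact 95% intervals of counts (Poisson) and of count ratios (conditional binomial) cover counting error only. Where a fold is given for a count of 0, that count was set to a floor of 3 counts per library. This floor is 0.278 CPM in the ME-180 control, 0.299 in the library labelled knockdown, 0.211 in the SiHa vector and 0.219 in the overexpression library. It is not a 95% limit, so the lower 95% limit is printed beside such folds.

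Before the data were examined, 29 gene lists were fixed, together with the rule for named genes: TP63, the 10 highest and 10 lowest log2 ratios per experiment among genes with at least 100 counts in a library, leaving out small RNA genes and unnamed loci, and up to 4 members per list with the largest ratio. The parts of the rule that needed peak scores or peak genes could not be applied. The median of each list with at least 5 measured genes was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and its percentile describes these 2 libraries only. Lists overlap, for example in KRT5 and KRT14. The overlap of the 2 experiments was set against the product of the list sizes divided by the genes at the floor in both. Libraries were compared over 13206 transcripts found in both tables. Peak spacing was compared with 200 random placements of the peaks within each chromosome's outermost peaks.

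The rules were tested on simulated counts with the real means and library sizes. The genes to change were drawn only from those with a mean of at least 5 CPM. With 100 genes raised and 100 lowered by 4-fold, 100 of 100 were called in each direction for both experiments. Of the unchanged genes, 2 in ME-180 and 1 in SiHa were called. Recovery of genes under 5 CPM, whose ratios the pseudocount shrinks, was not tested. Of 100 random lists without a change, 10 in ME-180 and 5 in SiHa fell outside the central 95% of matched lists, so percentiles near the edges are approximate. The simulation holds counting error only, not the spread between cultures.

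Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no floor and a floor of 5 CPM, thresholds of 1.5-fold and 4-fold, median centring, trimmed means of edgeR, size factors of DESeq2 1.42.0 and matching in 10 bins. Alternatives chosen after seeing the data were the authors' own scaling, summed transcripts, each transcript separately, totals without KRT5, merged or wider peaks, and the overlap without TP63. Work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3. The reference tables used here are of another build than the peaks, so peaks were not linked to genes. The input library was not analysed here. A few genes, and the result of 1 list that needs them, are not reported here.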

Results

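The series holds 6 samples of human cervical cancer cell lines, with 1 library per group. ME-180, a squamous cervical carcinoma line, gave a p63 chromatin immunoprecipitation, its input, and RNA from control cells and p63 knockdown cells. SiHa, another cervical carcinoma line, gave RNA from cells with a vector and from cells that overexpressed p63. p63, encoded by TP63, is a transcription factor of the p53 family that marks the basal layer of stratified epithelia. The tables used here held 10804272 counts for the ME-180 control, 10046579 for the library labelled knockdown, 14207637 for the SiHa vector library and 13690639 for the overexpression library. These are totals of the rows in the tables and were not taken as full sequencing depths. No group had a replicate, so every difference is between 2 libraries and its 95% interval covers counting error only.

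TP63 was almost absent from the library labelled knockdown and low but raised in the overexpression library. In ME-180, the delta N alpha transcript NM_001114980.1 had 5619 counts in the control and 6 in the library labelled knockdown, or 520 against 0.597 CPM (counts scaled to a library total of 1000000), an 871-fold lower level (95% interval 400 to 2374). In SiHa, the same transcript had 7 counts with the vector and 179 with overexpression, or 0.493 against 13.1 CPM, a ratio of 26.5 (12.6 to 67.0). The level of this transcript in SiHa stayed below the 520 CPM of the ME-180 control, and that of the delta N gamma transcript was 8.55 CPM against 47.2. The delta N gamma transcript NM_001114982.1 went from 510 counts to 0 in ME-180, 158-fold lower against a floor of 3 counts (lower 95% limit 128). In SiHa it went from 0 to 117 counts, 40.5-fold higher against that floor (lower 95% limit 32.4). A read can count for several overlapping TP63 transcripts, so the transcript counts are not independent. TP73, another member of the family, had a log2 ratio of -1.09 in ME-180.

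**Figure D1:**
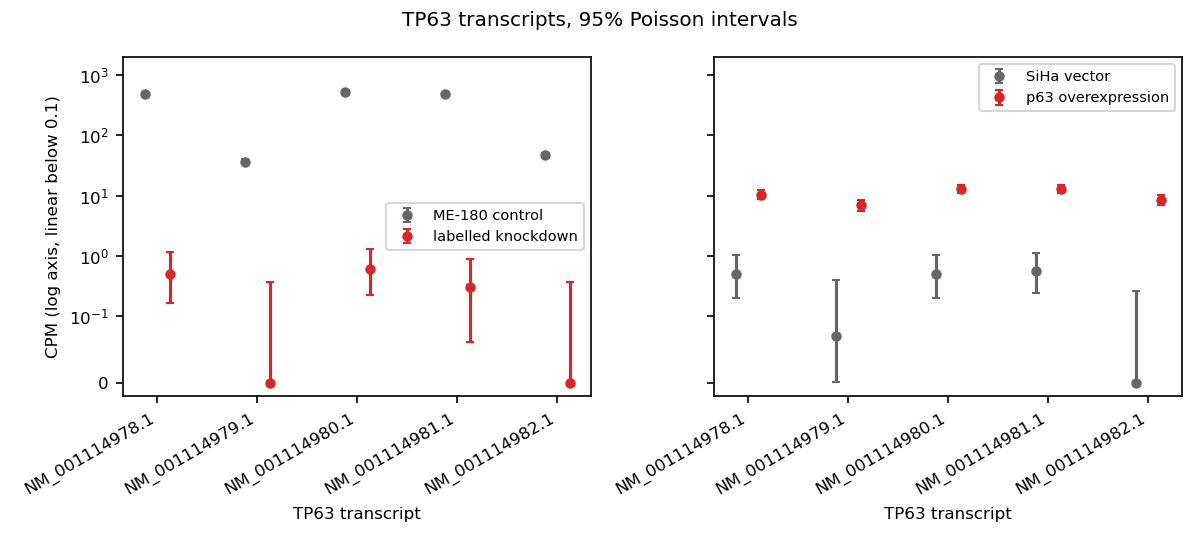
CPM of 5 TP63 transcripts (log axis, linear below 0.1) in the ME-180 libraries (left) and the SiHa libraries (right), 1 library each, with exact 95% Poisson intervals. The delta N alpha transcript NM_001114980.1 stands at 520 CPM in the ME-180 control and 13.1 CPM in the SiHa overexpression library.

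The knockdown comparison asks which transcripts change when p63 is reduced in ME-180. Genes of the basal squamous programme were the most strongly lower in the library labelled knockdown. KRT5, a keratin of basal keratinocytes, had 679522 counts in the control and 239 in the library labelled knockdown, 2644-fold lower (2329 to 3014). KRT14, its pairing partner, was 1440-fold lower (1008 to 2134), and COL17A1, a hemidesmosome collagen, was 1793-fold lower (1134 to 3025). PKP1, a desmosome plaque protein, had 9585 counts against 1, a ratio of 8913 with an interval of 1599 to 352070. The genes ELF3, an epithelial transcription factor, and KAL1 had 4952 and 5096 counts in the control and 0 in the library labelled knockdown, at least 1535-fold and at least 1579.5-fold lower. ARSI (log2 ratio -9.36), ANXA8 (-8.76), IGFBP3 (-8.72), an insulin-like growth factor binding protein, and TGFBI (-8.68), a matrix protein, completed the 10 lowest genes. ANXA8 has near-identical copies and the KRT5 and KRT14 genes have close paralogs, so counts of these genes can include reads of their copies.

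Of the 10 highest genes in the library labelled knockdown, all but CBS had 6 or fewer counts in the control. ALDH1L2, a mitochondrial folate enzyme, had 4 counts in the control and 2501 in the library labelled knockdown, a ratio of 672 (262 to 2470). LIN28B, an RNA-binding protein that blocks let-7 maturation, had 2 against 1981 counts, a ratio of 1065 (294 to 8802). GSTM3, a glutathione transferase, had 6 against 2457 counts (log2 ratio 7.30), and CBS, an enzyme of transsulfuration, 82 against 7255 (6.40). KIF1A, a kinesin of neurons, had 1 against 1055 counts, and ALDH1A2, an enzyme of retinoic acid synthesis, 1 against 878. The 4 genes ECI2, SMOC1, ARHGDIG and SLC35F1 had 0 counts in the control and 1029, 825, 810 and 795 in the library labelled knockdown, at least 369-fold, 296-fold, 290.4-fold and 285-fold higher. For ECI2 this holds for the 1 transcript in the table.

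Of 6783 genes with a row and at least 1 CPM in either ME-180 library, 1914 were at least 2-fold higher and 1400 at least 2-fold lower in the library labelled knockdown, together 48.9%. Common genes without a row, such as RPS2, are not among the 6783, so this is not a share of all expressed genes. The median log2 ratio of the 6783 genes was 0.28. Scaling by trimmed means, which subtracts 0.28, turned the share of higher genes among those changed from 57.8% to 47.6%. Over the transcripts with rows for both lines, the 2 ME-180 libraries were less alike than libraries of different cell lines. This set leaves out transcripts with 0 counts in both libraries of 1 line. That can raise the likeness between lines, so the comparison is not an even one. Across 5564 genes (which are not replicates), Pearson's r of log2(CPM + 1) was 0.644 between the ME-180 control and the library labelled knockdown, 0.735 between the control and the SiHa vector library, and 0.800 between the library labelled knockdown and the SiHa vector library. The SiHa pair had r = 0.989. Genes with at least 100 counts in 1 library and 3 or fewer in the other numbered 251 for the ME-180 pair, 109 for ME-180 control against SiHa vector and 1 for the SiHa pair. These values stand beside each gene group of the knockdown comparison. In the authors' deposited table, 5531 transcripts of 3497 genes had an adjusted p below 0.05, 2489 higher and 3042 lower. Those p-values matched an edgeR exact test with a preset biological coefficient of variation of 0.2 within 0.01 log10 units for 99.987% of transcripts, a preset value and not a spread between replicates.

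Among the gene lists fixed beforehand, most measured members of the epithelial lists were lower in the library labelled knockdown. The ME-180 table used here has rows for 11 of 26 basal, 8 of 28 desmosome, 12 of 25 epithelial identity and 24 of 38 squamous differentiation genes. It has 9 of 27 squamous transcription factor and 21 of 44 literature target genes. Other lists also lack members, with 13 of 25 housekeeping, 15 of 36 cell cycle and 9 of 25 p53 pathway genes present. A gene without a row cannot be read as not expressed, and the shares below are of measured genes. Of the basal squamous keratins and adhesion genes, 11 of 11 measured were lower, with a median log2 ratio of -8.04, below all 10000 random lists matched on expression (percentile 0), and KRT17 had a log2 ratio of -8.42. The epithelial identity list was lower in 12 of 12 genes (median -4.71, percentile 0), among them SPINT1 (2034 counts against 0), PROM2 (-6.99) and CLDN7, a claudin (-6.86). Of the desmosome and cell junction genes, 7 of 8 were lower (median -4.11, percentile 0), with GJB6, a gap junction connexin, at -8.49. The squamous differentiation list was lower in 18 of 18 genes (median -1.99, percentile 0), led by the cornified envelope transglutaminase TGM1 at -7.63, and ECM1 at -3.94. Of the squamous transcription factors, 7 of 8 were lower (median -3.16, percentile 0.05), with EHF at 4298 counts against 0 and GRHL3 at -3.20. Of the p63 targets known from the literature, 13 of 21 were lower and 3 higher (median -2.04, percentile 0), with HAS3, a hyaluronan synthase, at -6.11. This list was fixed without a direction per gene, so its low median does not test the known effects of p63. The simple epithelium keratins KRT8 (-6.38) and KRT18 (-2.87) were also lower, in a glandular list with 6 of 8 lower (median -1.14, percentile 3.21).

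Signalling and stress lists were mixed or lower in the same comparison. The NF-kB and inflammatory cytokine list had 8 of 13 genes lower and 3 higher (median -2.29, percentile 0.05), with the interleukin antagonist IL1RN at -6.94 and IL1A at 248 counts against 0. Of the interferon-stimulated genes, 10 of 14 were lower and 1 higher (median -1.89, percentile 0.11), with OAS1 and OAS2 at 254 and 166 counts against 0. Growth factor signalling genes were lower in 14 of 20 and higher in 2 (median -1.99, percentile 0), with TGFA at -3.53 and SPRY1 at 2.83. TGF-beta and YAP targets were lower in 8 of 14 and higher in 2 (median -1.30, percentile 0.18), with BMP2 at -7.16 and SMAD3 at -3.36. Proteases were lower in 9 of 14 and higher in 1 (median -2.12, percentile 0.01), with SERPINB2 at 1708 counts against 0 and PLAU at -4.87. Oxidative stress genes were lower in 7 of 11 (median -2.23, percentile 0), with ALDH3A1 at -8.17 and NQO1 at -6.47. The hypoxia and glycolysis list had 8 of 17 lower (median -0.55, percentile 0.41), with ADM at -6.18 and NDRG1 at -4.71. Notch pathway genes split, with 5 of 9 lower and 2 higher (median -2.17, percentile 0.01), JAG1 at -4.68 and the target HEY1 at 4.71.

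The remaining lists in ME-180 held genes that moved in either direction or did not pass the rule. ZEB1 and ZEB2, repressors of epithelial genes, had 1 count each in the control and 179 and 223 in the library labelled knockdown, while TGFBI was lower, and the epithelial-mesenchymal transition list had 4 of 13 higher and 4 lower (median 0.22, percentile 42.2). Of 5 fibroblast markers, 3 were higher and 1 lower (median 1.80, percentile 98.1), with FBN1 at 4.07, COL3A1 at 3.24 and COL1A1 at -1.27. The unfolded protein response list had 4 of 7 higher and 1 lower (median 1.40, percentile 97.51), with CHAC1 at 5.45 and ASNS, asparagine synthetase, at 4.40. Sterol and fatty acid synthesis genes were higher in 6 of 12 and lower in 1 (median 0.84, percentile 96.1), with ACLY at 2.31 and SREBF1 at -3.25. Ribosomal protein genes were higher in 7 of 31 and lower in 0 (median 0.56, percentile 92.0), with RPL5 at 1.47. The p53 pathway had 4 of 9 higher and 2 lower (median -0.35, percentile 9), with BBC3 at 2.85 and DDB2 at -1.53. The WNT list had 3 of 8 higher and 3 lower (median 0.38, percentile 56.6), with LEF1 at 3.15 and DKK3 at -4.74. Cell cycle genes had 2 of 15 higher and 1 lower (median 0.08, percentile 19.1), with CCNE1 at 1.94 and TOP2A at -1.35. Immediate early genes had 2 of 7 higher and 1 lower (median 0.12, percentile 46.8), with ATF3 at 1.96. Immune cell markers had 1 of 5 higher and 1 lower (median -0.40, percentile 33.6), with CD68 at -3.42. Both measured replication-dependent histone genes were lower, HIST1H4H at -2.44 and HIST1H1B at -1.79. Housekeeping genes had 1 of 13 higher and 1 lower (median 0.34, percentile 54.4), with TBP at 1.30 and GAPDH at -1.25.

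Several medians depend on genes at 0, on the pseudocount, on the floor or on the scaling. The squamous differentiation median in ME-180 was -4.59 with a pseudocount of 0.1 and -0.69 with a pseudocount of 5. Without the floor of 1 CPM, the ME-180 medians were -0.87 for NF-kB and -1.02 for proteases. With genes at 0 set to 3 counts and no pseudocount, the ME-180 medians were -8.58 for basal genes, -2.95 for squamous differentiation, -5.66 for squamous transcription factors, -5.44 for epithelial identity, -2.10 for literature targets, -2.41 for the glandular list, -2.72 for NF-kB, -2.58 for interferon genes, -2.04 for growth factor signalling, -1.31 for TGF-beta and YAP, -2.17 for proteases, -2.54 for oxidative stress, -0.55 for hypoxia, 3.16 for fibroblast markers, 0.23 for epithelial-mesenchymal transition and 0.40 for WNT genes. Under the authors' scaling the medians of the cell cycle (-0.24), epithelial-mesenchymal transition (-0.09) and immediate early (-0.04) lists turned below 0.

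The overexpression comparison asks which transcripts change when p63 is raised in SiHa. Basal keratinocyte genes were higher and inflammatory cytokines lower in the overexpression library. KRT14 rose from 23 to 392 counts, a ratio of 17.7 (11.6 to 28.2), COL17A1 from 20 to 107 counts, a ratio of 5.55 (3.42 to 9.45), KRT5 from 247 to 730 counts, 3.07-fold (2.65 to 3.56), and KRT15, another basal keratin, from 679 to 2063 counts, 3.15-fold (2.89 to 3.44). KRT19, a keratin of simple epithelia, was 2.89-fold higher (2.78 to 2.997). CXCL8, a neutrophil chemokine, fell from 401 to 2 counts, a 193-fold lower level (53.1 to 1601), and IL6, an inflammatory cytokine, from 415 to 33 counts, 12.1-fold (8.49 to 17.8).

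The other genes among the 10 highest were TP63 itself, CACNA2D1, a calcium channel subunit (log2 ratio 2.01), CADPS2 (1.69), CD74, the invariant chain of class II antigen presentation (1.65), and TRIM22, an interferon-induced gene (1.60). The lowest also included TLX1, a homeobox gene (-1.99), PTGS2, the inducible prostaglandin synthase (-1.81), 1 transcript of INPP5F (-1.67), PTX3, a pentraxin of inflammation (-1.56), NPAS2 (-1.37), VPS37D (-1.32), ALDH1L2 (-1.31) and MAGED4 (-1.25). MAGED4 has a near-identical copy and the KRT14 counts can include reads of paralogs. Of 6996 genes with at least 1 CPM in either SiHa library, 40 were at least 2-fold higher and 52 at least 2-fold lower, together 1.32%. In the authors' deposited table, 22 transcripts of 16 genes had an adjusted p below 0.05, 15 higher and 7 lower, with the same preset variation as in ME-180. The count of 40 and 52 became 113 and 227 with a pseudocount of 0.1 and 14 and 6 with a pseudocount of 5.

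Among the fixed lists in SiHa, the medians of the basal, squamous differentiation, glandular and epithelial identity lists lay above the random lists, with most members short of the 2-fold rule. Of 19 basal squamous keratin and adhesion genes, 7 were higher and 0 lower (median 0.51, percentile 100, and 0.27 with a pseudocount of 5). Squamous differentiation had 2 of 9 higher, KRT13 at 1.47 and S100A9 at 1.20, and 8 of 9 above 0 (median 0.97, percentile 100). This median was 0.20 with no floor and 0.44 with a pseudocount of 5. In the glandular list 1 of 6 was higher, KRT19, and KRT8 had a log2 ratio of 0.87 (median 0.67, percentile 100, and 0.41 with no floor). Epithelial identity genes passed the size rule in 0 of 13 but lay above 0 in 11 (median 0.27, percentile 99.98). The desmosome list had 0 of 15 past the rule (median 0.06, percentile 93.6), with DSP, desmoplakin, at 0.67, and squamous transcription factors 0 of 12 (median 0.07, percentile 93.7), with EHF at 0.87. Literature p63 targets were higher in 2 of 26, KRT14 and KRT5 (median -0.01, percentile 77.4).

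Inflammatory, immediate early and growth lists lay below 0 in SiHa. NF-kB and inflammatory cytokine genes were lower in 7 of 18 (median -0.76, percentile 0, -0.84 with the gene at 0 set to 3 counts, and -0.39 with a pseudocount of 5 or no floor), with CXCL1 at -1.77. Of the immediate early genes, 0 of 9 passed the rule and all 9 lay below 0 (median -0.56, percentile 0), with ATF3 at -0.99, EGR1 at -0.93 and JUN at -0.78. The following lists had 0 genes past the rule and a median at the low edge of the random lists. They were the unfolded protein response (median -0.40, percentile 0.12, CHAC1 at -0.92), growth factor signalling (-0.22, percentile 0.6, IGF1R at -0.68), hypoxia and glycolysis (-0.22, percentile 0, PDK1 at -0.65), cell cycle (-0.14, percentile 0.22, CDK1 at -0.45 and MKI67 at -0.40) and ribosomal proteins (-0.13, percentile 0, RPS24 at -0.44). All of these medians stayed below 0 under each scaling tried.

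The remaining lists showed small or mixed ratios in SiHa. Fibroblast markers had 1 of 6 higher, POSTN with 1 against 20 counts (median 0.34, percentile 99.2), and COL1A1 at -0.68. Immune cell markers had 1 of 4 higher, CD79A with 1 against 21 counts (median 0.33). Epithelial-mesenchymal transition genes had 1 of 22 higher and 2 lower, FN1 at -1.06 and ZEB2 at -1.04 (median -0.08, percentile 30.2). The p53 pathway had 0 of 11 past the rule (median 0.10, percentile 97.6), with the cell cycle inhibitor CDKN1A at 0.61. No gene passed in the lists of WNT (median -0.23, percentile 8.43, SFRP1 at -0.76), Notch (-0.14, percentile 22.7, NRARP at -0.73), sterol synthesis (-0.08, percentile 11.6, ELOVL6 at -0.29) and proteases (-0.09, percentile 38.2, PLAT at -0.88). Medians within 0.05 of 0 were found for TGF-beta and YAP targets (-0.03, percentile 53.3), interferon-stimulated genes (0.00, percentile 77.8), oxidative stress (-0.03, percentile 36.7), replication-dependent histones (-0.03, percentile 67.8) and housekeeping genes (-0.00, percentile 43.7). The mitochondrial encoded genes of the last list had 0 rows in either table used here.

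**Figure D2:**
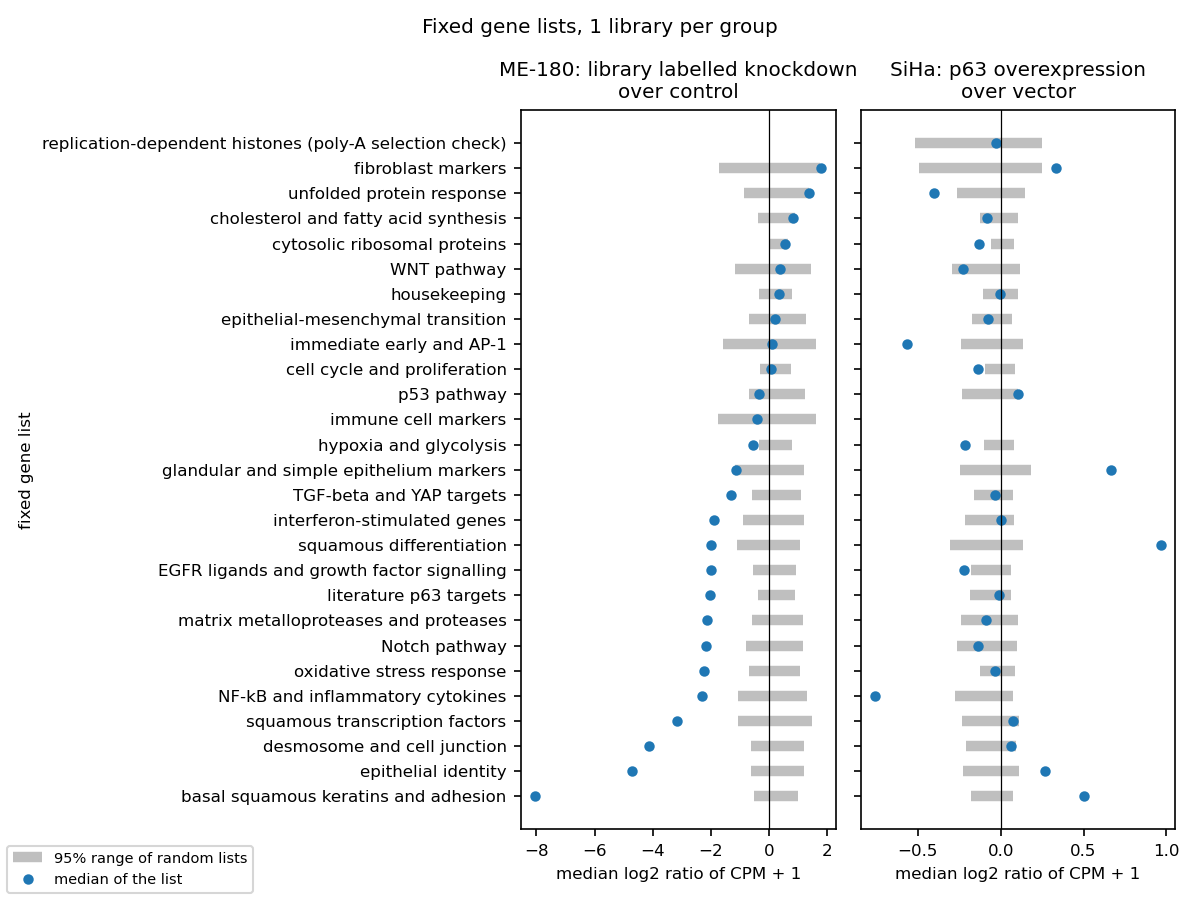
Median log2 ratio of CPM + 1 of each fixed list with at least 5 measured genes (points), beside the 95% range of 10000 random lists matched on expression (grey bars), in ME-180 (left) and SiHa (right), 1 library per group. The basal list has medians of -8.04 and 0.51, and the NF-kB list -2.29 and -0.76; the 2 panels have different axis ranges.

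Set side by side, the 2 experiments shared genes that changed in opposite directions, among them several basal keratinocyte genes. Of 5573 genes at 1 CPM or more in both, 14 were lower in the library labelled knockdown and higher with overexpression, against 3.69 for independent lists of these sizes. They included TP63, KRT14, KRT5, KRT17, COL17A1, ITGB4, the integrin partner in hemidesmosomes (log2 ratios -7.65 and 1.14), ARHGDIB (-7.83 and 2.43), FAM134B (-2.86 and 1.51) and TRIM22 (-4.19 and 1.60). Other basal genes did not, such as ITGA6, with log2 ratios of -3.32 and -0.30, and COL7A1, with -3.70 and -0.38. Another 20 genes were higher in the library labelled knockdown and lower with overexpression, against 9.53 for independent lists, among them ALDH1L2, LIN28B, PTX3, TENM1, NFATC4 and ZEB2. These named genes were picked from the opposite groups after their values were seen, except those named above. Genes lower in both numbered 5 against 5.45, PTGS2, CCL20, FUT1, ANG and GJA1, and genes higher in both 5 against 6.45, CACNA2D1, CADPS2, FCRLB, CCDC173 and ASAH2B. Across the 5573 genes, Pearson's r of the log2 ratios was -0.286 and Spearman's rho -0.198, as a description, since genes are not independent replicates. The group of 20 numbered 0 genes with a pseudocount of 5 and 10 with a floor of 5 CPM, and the group of 14 numbered 8 and 11.

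**Figure D3:**
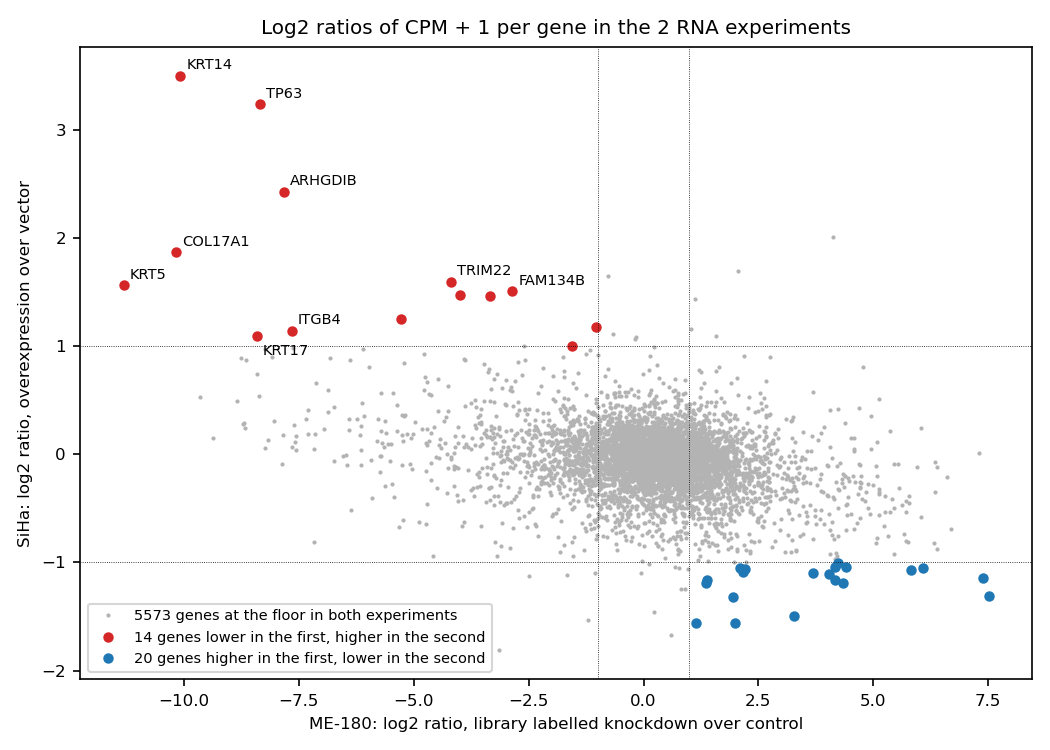
Log2 ratios of CPM + 1 of 5573 genes in ME-180 (x axis, library labelled knockdown over control) and SiHa (y axis, overexpression over vector), with dotted lines at the 2-fold rule. The 14 red genes, KRT14 and TP63 at the top, lie in the upper left and the 20 blue genes in the lower right.

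The chromatin immunoprecipitation asks where p63 is bound in ME-180. The deposited list held 6466 peaks on build hg19, with positions only and no score, so peaks could not be ranked by strength. They covered 1.55 Mb, had a median width of 250 bp (range 100 to 1000) and were at most 300 bp wide in 88.0%. Chromosome 19 held the most peaks per length, 470 peaks or 7.97 per Mb between its outermost peaks, followed by chromosome 22 with 4.61 and chromosome 17 with 4.29, against 2.19 over all chromosomes. Chromosome 4 had 1.19 per Mb, and the lowest was chromosome Y with 6 peaks or 0.279 per Mb. Why the list of this cervical line holds peaks on chromosome Y was not tested.

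Peaks lay in close groups more often than random positions did. Gaps of at most 500 bp between neighbouring peaks numbered 409, against a mean of 13.2 and a maximum of 24 in 200 random placements. Gaps of at most 5000 bp numbered 820 against a mean of 91.7. The placements were even along each chromosome and took no account of where genes or mappable sequence lie. The excess therefore cannot be read as particular to p63, and peaks of no other factor were compared. Whether close peaks are parts of 1 region was not tested. The densest window of 1 Mb was chromosome 15 from 25000000 to 26000000 with 27 peaks, followed by chromosome 19 from 10000000 to 11000000 with 23. The largest run of peaks less than 5000 bp apart was on chromosome 14 from 101521350 to 101532999 with 5 peaks. The widest peak was on chromosome 7 from 90893700 to 90894699, and the next on chromosome 17 from 29248050 to 29248949. No annotation of hg19 was used here, so peaks were not assigned to genes, exons or promoters, and genes near p63 binding sites were not analysed here in the RNA tables.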

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

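The authors' scaling, summed or separate transcripts, totals without KRT5, other peak sets and the overlap without TP63 were chosen after the results were seen. None of the 231 named log2 ratios changed sign under any setting run. A pseudocount or a floor cannot change the sign of a gene's ratio, so only the scalings, summed transcripts and totals without KRT5 could. The genes were also named for their large ratios, so this stability is partly built in. Of 52 list medians, 11 changed sign under at least 1 setting, none of them outside the central 95% of its random lists. Counts of changed genes moved with the pseudocount, the floor and the threshold. A pseudocount of 0.1 gave 113 higher and 227 lower genes with overexpression, and opposite groups of 41 (independent lists 11.1) and 84 (42.1). A pseudocount of 5 gave 1272 higher and 918 lower genes in the library labelled knockdown, 14 and 6 with overexpression, and opposite groups of 8 (1.44) and 0 (0.649). A floor of 5 CPM gave 24 higher and 28 lower genes with overexpression and 10 genes higher and then lower (4.50). At 1.5-fold, overexpression gave 157 higher and 396 lower genes and opposite groups of 68 (23.0) and 164 (112). At 4-fold, the knockdown comparison gave 598 and 671, overexpression 4 and 2, and the opposite groups 3 and 0. Each transcript on its own gave 3176 higher and 2375 lower in the library labelled knockdown and 23 in the first opposite group, since more rows were counted. Higher or lower counts and both opposite groups stayed within 1.5 times under the 4 scalings, totals without KRT5 and summed transcripts. The share of higher genes among those changed in ME-180 was 57.8% with totals, 46.2% with the median set to 0, 47.8% with DESeq2 size factors and 46.3% with the authors' scaling, which shifts ratios by 0.32.

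The log2 ratio of TP63 was -6.55 in ME-180 and 1.72 in SiHa with a pseudocount of 5, and 4.47 in SiHa with 0.1. With a pseudocount of 0.1, ME-180 medians were -4.59 for squamous differentiation, -5.01 for squamous transcription factors, -3.60 for the glandular list and 4.14 for fibroblast markers. With a pseudocount of 5 they were -6.07 for basal genes, -3.13 for desmosomes, -0.69 for squamous differentiation, -1.81 for squamous transcription factors, -1.27 for literature targets, -3.29 for epithelial identity, -1.14 for Notch, -1.09 for growth factor signalling and -1.17 for oxidative stress, and in SiHa 0.27 for basal genes, 0.44 for squamous differentiation and -0.39 for NF-kB. Without a floor, NF-kB (-0.87) and proteases (-1.02) moved in ME-180, and squamous differentiation (0.20), the glandular list (0.41) and NF-kB (-0.39) in SiHa. With a floor of 5 CPM squamous differentiation in ME-180 was -3.71. The cause of these moves was not tested beyond the shrinkage that a larger pseudocount gives. Without a floor the counts of genes could not change, since a 2-fold ratio with a pseudocount of 1 needs 1 CPM. Matching in 10 bins moved percentiles by at most 3.84 points. Without TP63 the first opposite group had 13 genes. Peaks numbered 6057 after merging within 500 bp and 5214 at 200 bp or more. Peak scores, promoter and distance alternatives were not run, because the list has no scores and no annotation of its build was used here. No paired analysis was possible because each group has 1 library, which also leaves the spread between cultures unknown.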

Other observations

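All tests in this part were chosen after the results were seen, as were the genes named in the next paragraph. Some chemokines beyond CXCL8 and CXCL1 were lower in the SiHa overexpression library and others were not: CXCL3 had 46 counts with the vector and 6 with p63, CXCL2 87 and 24, CCL20 27 and 0, but CCL2 22 and 51 (log2 ratio 0.89) and CCL5 162 and 141 (-0.13). CIITA, the activator of class II antigen presentation genes, was higher with 66 against 141 counts, together with CD74. HLA-DRB1 had a log2 ratio of 0.54, HLA-DPB1 -0.34 and HLA-DQB1 -0.27, so the class II genes did not share a direction, and reads of HLA genes can be split between close copies. Hemidesmosome genes also parted: ITGB4 was higher (log2 ratio 1.14) while its partner ITGA6 was at -0.30, and LAMB3, a laminin chain, was at 0.54.

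Genes with the largest ME-180 ratios tended to go the other way in SiHa, while most genes lower in ME-180 showed little common direction there. Among genes with at least 100 counts summed over the SiHa libraries, the 76 with an ME-180 log2 ratio below -5 had a median SiHa log2 ratio of 0.23, and 59 lay above 0. The 113 genes between -5 and -3 had a median of 0.07 (68 above 0 and 45 below), and the 504 between -3 and -1 a median of 0.01 (261 above and 243 below). The 2821 genes with an ME-180 ratio between -1 and 1 had a median of -0.02, the 1096 between 1 and 3 -0.07 and the 87 between 3 and 5 -0.28. The 36 genes at 5 or more had a median of -0.45, and 31 lay below 0.

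The first pattern is the distance between the 2 ME-180 libraries. KRT5 took 6.29% of the control counts, so leaving it out of both totals can shift the log2 ratios only slightly. The median log2 ratio moved from 0.28 to 0.20, and 3235 genes passed the 2-fold rule against 3314. A share of this size does not account for the difference, but the small shift fixed that count in advance, so it is no separate evidence. A library from other cells than the control is a candidate explanation: r between the 2 ME-180 libraries was 0.644, below the 0.735 between control libraries of different lines. Both values cover only transcripts with rows for both lines, a choice that can raise the likeness between lines. The comparison is therefore not an even one and does not decide the question. A loss of p63 in the same cells stays open, since the tables set no limit to its reach. That TP63 was almost absent does not separate the explanations, because other cells without p63 would show it too. A loss of p63 would have to switch 251 genes off or on, against 109 between the lines, counted over the same transcripts and with the same limit. Which of these holds cannot be told apart with 1 library per group, and each knockdown result above carries this doubt.

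The second pattern is that genes high in the library labelled knockdown were lower with overexpression. With another definition, 46 genes under 1 CPM in the control and at 30 CPM or more in the library labelled knockdown, 40 lay below 0 in SiHa (median -0.50). RNA like that of the library labelled knockdown in the SiHa libraries could lower them together if its share fell. Over these 46 genes the vector library allows a share of at most 6.88%, set by DDR2 alone. Genes with 0 counts in both SiHa libraries have no row there and could not enter, so a lower limit could not be seen. Of the 36 genes, 11.1% (LIN28B, TENM1, SMOC1 and SMIM10) lost more than 6.88% beyond counting error. Around 1 common share lost, the chi-square over degrees of freedom was 7.99, above the 2 that this explanation predicted, but it measures against counting error only, so the explanation is weakened and stays open. A response to p63 in both lines also stays open: 34 genes, TP63 included, changed in opposite directions against 13.2 for independent lists. In the direction of this pattern there were 20 against 9.53, and 0 against 0.649 with a pseudocount of 5. The doubt about the library labelled knockdown applies to this explanation too.

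The third pattern is the makeup of TP63 counts in SiHa: delta N gamma counts were 66.1% of delta N beta counts with overexpression (95% interval 51.9% to 84.0%) and 9.58% in the ME-180 control (8.73% to 10.5%). A construct without the 3 prime part of the long transcripts is a candidate explanation, since it would raise this share, although a different spread of reads along transcripts was not tested. A construct of the gamma form would give at least as many gamma as beta counts, beyond the cells' own, of which the vector library had 8 for beta. Taking off 16, their upper limit, leaves gamma at 72.7% of beta with an upper limit of 92.8%, which argues against such a construct with the cells' own transcripts at the vector level. With own transcripts raised by p63 it stays open and was not tested, and the intervals treat overlapping counts as separate.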
